A study of Arabidopsis thaliana with 18 samples.

How the data were processed

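Poly(A) RNA of whole Arabidopsis thaliana seedlings (ecotype Col-0) was measured by RNA sequencing in 18 libraries. Per the labels' protocols, wild type, als3-1 and sog1-7 seedlings were grown in constant light on soaked gel medium of pH 4.2 with 0 or 1.5 mM AlCl3, and were collected 84 h after sowing. The libraries fall into 6 groups of genotype and AlCl3 concentration with 3 libraries each, and the labels number the replicates 2, 3 and 4. Libraries are named here by genotype, concentration and replicate, as in "wild type 0 mM replicate 3". Nothing in the labels says that the samples of a group are separate cultures, so the p-values measure only the spread between these samples, which may be technical.

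The deposited count values are whole-number reads per gene, which, per the file headers and the submitters' processing notes, came from featureCounts 2.0.0. The deposited FPKM values are fragments per kilobase of gene and per 1e6 mapped fragments, and the submitters' processing notes name Cufflinks 2.2.1. Those notes also name FastQC 0.11.7, STAR 2.7.3a, DESeq2 1.36.0 and the genome build TAIR10. The libraries were made with a directional kit, per the labels' protocols. The strand setting of the counting, the rule for reads that map to several places and the annotation release are not given in the sources used here. Values of antisense or overlapping genes and of near-identical copies are therefore uncertain, which covers the tandem genes AT5G46890 and AT5G46900, AT1G13608 and AT1G13609, BGLU21 and BGLU22, GSTF6 and GSTF7, and the genes of the light-harvesting proteins. Of 32538 genes present in both the FPKM files and the reference annotation, 32519 had the same start and end (99.94%). Coordinates given here are TAIR10, and gene symbols came from the reference annotation. The count files list 32833 genes, and all 285 genes of the plastid and mitochondrial genomes stood at 0 in every library.

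The total count per library was 25.56 to 44.57 (median 35.09) in units of 1e6 reads. A level of 3 counts corresponded to 0.0673 to 0.117 counts per 1e6 counts (CPM) in a single library, and differences below that level were not detectable at this depth. Intervals of ratios cover counting error only. The 18 pairs of libraries within a group were compared by a chi-square statistic over genes with at least 20 counts in the pair, and the lowest value per degree of freedom was 16.98, so no library was a copy of another of its group within sampling noise. Pairs across groups were not compared. The share of reads on 4 ribosomal RNA genes was 0.909% to 5.72% in 15 libraries and 0.0168% to 0.0286% in 3 libraries, als3-1 1.5 mM replicate 2, sog1-7 0 mM replicate 2 and sog1-7 1.5 mM replicate 2. These 3 libraries are called the low-rRNA libraries.

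Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, the default filterByExpr filter by group and a robust fit of 1 mean per group over all 18 libraries. The filter left 21650 genes, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.214. Group levels are given as mean CPM ± SD over 3 libraries, and changes as log2 fold changes ± SE. The contrasts were 1.5 against 0 mM within each genotype, the differences of these responses between genotypes, als3-1 against sog1-7 at 1.5 mM, and each mutant against wild type at 0 mM. The contrasts of each mutant against wild type at 1.5 mM were added after the data had been examined. The fold change of a gene with 1 to 3 counts in a group was replaced by a ratio of summed counts with an exact 95% interval.

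Before the data were examined, 20 gene lists with 317 members were fixed. They covered the DNA damage response, the root stem cell niche with the regeneration genes around ERF115, G2/M phase, S phase, endocycle regulators, aluminium resistance, phosphate starvation, iron supply, oxidative stress, root hairs, suberin and the endodermal barrier, xylem, ethylene and auxin, defence, abscisic acid, heat shock, photosynthesis, seed proteins, mobilisation of seed reserves, and root tissue. The photosynthesis, seed, reserve and root lists served as markers of other organs or of seedling age. Of the 317 members over all lists, 6 were dropped because identifier and symbol did not match in the reference annotation. For each list, members called over all genes and adjusted over the list alone were counted. The lists were tested with camera of limma 3.58.1 on log CPM values with a preset correlation of 0.01, and again with an estimated correlation and with fry. With the preset correlation 76 results over the 20 lists and 9 comparisons passed, and 10 of them passed with an estimated correlation. These 10 were aluminium resistance in all 3 Al responses, suberin in wild type and sog1-7, the DNA damage list in the differences of sog1-7 from als3-1 and from wild type and in als3-1 against sog1-7 at 1.5 mM, and iron supply in the difference of sog1-7 from wild type and in als3-1 against sog1-7 at 1.5 mM. Of these 10, only aluminium resistance still passed with an estimated correlation without the low-rRNA libraries, and phosphate starvation in sog1-7 passed there (adjusted p = 0.0243).

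The rule for named genes was also fixed before the data were examined. It names SOG1, ALS3 and ERF115. It names the 10 highest and 10 lowest fold changes (5 and 5 in the smaller comparisons) among called genes with a mean log CPM of at least 1 and no overlap between the samples compared, and up to 4 called members of each list. No overlap of 3 against 3 samples has a chance share of 10%. Genes without a known function, or with only a family name, were mostly left out, and list members whose call ended in a fit without 1 library were mostly left to the counts, a choice made after the values were seen. Genes of the added contrasts were chosen after their values were seen. Of the genes that the fold-change part of the rule named, 38 of 131 gene and comparison pairs were left unnamed.

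The replicate numbers were checked as pairs by correlating the deviations of same-numbered libraries from their group means. For wild type the correlations between 0 and 1.5 mM were 0.24 to 0.27, for als3-1 0.21 to 0.37 and for sog1-7 0.53 to 0.76. They were 0.44 to 0.72 between als3-1 and sog1-7 at 1.5 mM, 0.40 to 0.49 between wild type and als3-1 at 0 mM, 0.20 to 0.26 between wild type and als3-1 at 1.5 mM and 0.22 to 0.29 between wild type and sog1-7 at 1.5 mM. Every pair in these comparisons lay above 0.1, so the count of a fit with the replicate number as a block is given beside each of their counts. The pairing comes from the replicate numbers in the sample titles and this correlation. Of the list tests, only camera with the preset correlation was repeated with this block. The list values with an estimated correlation and with fry therefore do not use the pairing.

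Alternatives fixed beforehand were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0, the replicate block, a fit of only the groups compared, a minimum change of 2-fold, limma on log2(FPKM + 1), and leaving out each library in turn. Added after seeing the data were fits without the low-rRNA libraries, with a term for them, and with that term and the replicate block. On the FPKM scale the median over all tested genes was shifted up against the counts by 0.144 in als3-1 against wild type and 0.184 in sog1-7 against wild type at 0 mM, and by 0.172 and 0.20 in the same comparisons at 1.5 mM (log2), and the other comparisons were shifted by at most 0.054. The scripts were tested on simulated counts with 200 changed genes per run. All groups shared the same mean and dispersion per gene, apart from the changed genes in the group tested. No replicate or low-rRNA effect was simulated. At a true change of 2-fold, 50.0% of the tested changed genes were recovered for the Al response in wild type (21456 genes), 63.6% in als3-1 (21428 genes) and 52.2% in sog1-7 (21471 genes), and 30.3% for the difference between als3-1 and sog1-7 (21428 genes). At 4-fold these shares were 89.4%, 93.9%, 89.4% and 75.8%.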

Results

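ERF115 (AT5G07310, chromosome 5, 2305551 to 2306837), a transcription factor of stem cell replenishment, rose with 1.5 mM AlCl3 by 5.27 ± 0.57 log2 units in als3-1 (adjusted p = 2.32e-05, n = 3 against 3). In als3-1 it went from 7 counts over 3 libraries at 0 mM to 315 at 1.5 mM. In wild type it went from 3 to 32 counts, a ratio of 10.6 (95% counting interval 3.33 to 54.3), and its call there (adjusted p = 0.0287) ended without any 1 of the 6 libraries (adjusted p = 0.0571 to 0.126). In sog1-7 it went from 3 to 13 counts, a ratio of 3.89 (1.07 to 21.3), and was not called (adjusted p = 0.495). The difference of the Al response between als3-1 and sog1-7 was not called for ERF115 (adjusted p = 0.354), and at 1.5 mM ERF115 was 4.65 ± 0.52 higher in als3-1 than in sog1-7 (adjusted p = 7.36e-05). SOG1 (AT1G25580, chromosome 1, 8996714 to 8999917), the transcription factor of the DNA damage response that gave sog1-7 its name, was not called in any comparison and had 13.6 to 19.5 CPM over the 18 libraries. ALS3 (AT2G37330, chromosome 2, 15669131 to 15670187), which gave als3-1 its name, had 3.28 ± 0.276 CPM in wild type and 3.29 ± 0.65 CPM in als3-1 at 0 mM. These 2 transcripts therefore do not check the genotype labels.

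ALS3 rose with Al in als3-1 (1.03 ± 0.27) and in sog1-7 (1.28 ± 0.28), and reached 0.98 ± 0.28 in wild type without a call (adjusted p = 0.101). Its call in als3-1 (adjusted p = 0.0232) ended without 0 mM replicate 2 or 4 or 1.5 mM replicate 3 or 4 (adjusted p = 0.0554 to 0.104). Its call in sog1-7 (adjusted p = 0.0332) ended without 0 mM replicate 2, 3 or 4 or 1.5 mM replicate 3 or 4 (adjusted p = 0.0593 to 0.164).

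**Figure D1:**
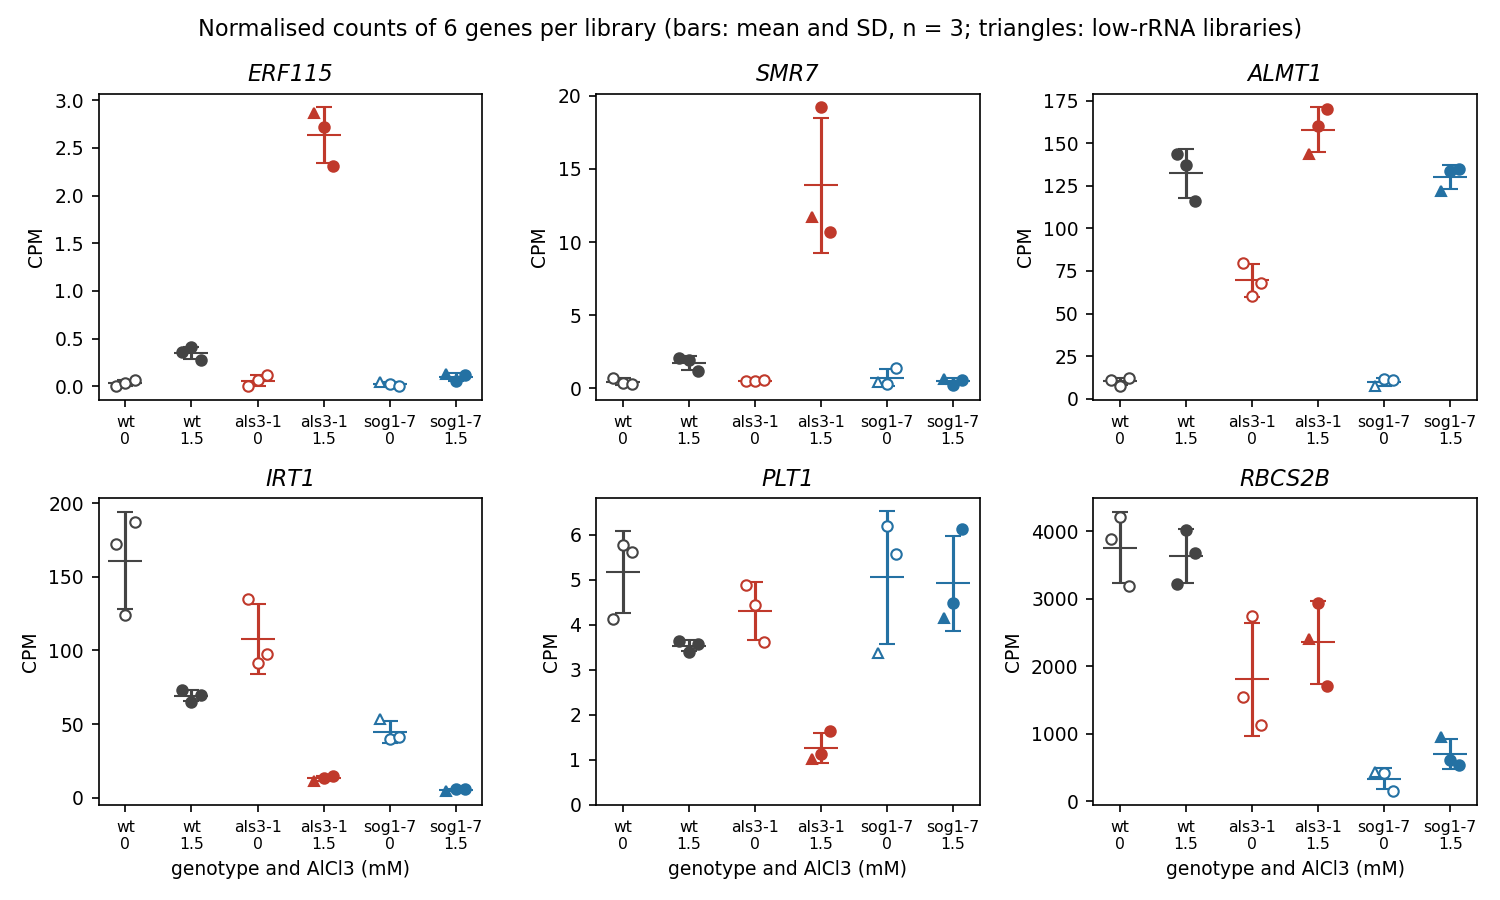
Level in CPM of ERF115, SMR7, ALMT1, IRT1, PLT1 and RBCS2B in each library. Open points are 0 mM and filled points 1.5 mM AlCl3, triangles are the low-rRNA libraries, and bars give the mean ± SD of 3 libraries per group.

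In wild type, ALMT1 (AT1G08430, chromosome 1, 2658602 to 2661310), the malate transporter of the root, rose with Al from 10.1 ± 2.29 to 133 ± 14.6 CPM (3.72 ± 0.20, adjusted p = 1.1e-07, n = 3 against 3), and the citrate transporter MATE (AT1G51340) rose by 2.09 ± 0.24. Among called genes with a mean log CPM of at least 1 and no overlap between the samples, larger rises were those of the RAD3-like helicase gene AT1G20750 (4.03 ± 0.62) and of TIL2 (AT2G27120), a catalytic subunit of DNA polymerase epsilon (3.91 ± 0.32). The potassium transporter HAK5 (AT4G13420) rose by 3.10 ± 0.33, the chitinase family gene AT2G43590 by 3.05 ± 0.19, and ABCA10 (AT5G61740), an ABC transporter, by 2.85 ± 0.35. The glutamate receptor GLR2.3 (AT2G24710) fell by 4.76 ± 0.50, and the sulfate transporter SULTR1;1 (AT4G08620) fell by 3.10 ± 0.41. The wall-associated kinase WAK4 (AT1G21210), PCR5 (AT3G18450) and the amino acid transporter UMAMIT29 (AT4G01430) fell by 2.99 ± 0.36, 2.66 ± 0.45 and 2.53 ± 0.42. The papain family protease genes AT1G29090 and AT4G36880 fell by 3.68 ± 0.39 and 2.81 ± 0.23. Over all genes 408 were called, 194 higher and 214 lower, and 293 of them changed at least 2-fold. The count was 803 with the replicate block and 499 without the low-rRNA libraries. It was 227 or 243 without wild type 0 mM replicate 3 or 4, and 212 without 1.5 mM replicate 4.

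Of the aluminium resistance list, 5 of 19 genes were called higher and 2 lower in wild type (9 and 2 adjusted over the list alone), and GDH1 (AT5G18170), a glutamate dehydrogenase, rose by 1.13 ± 0.14. Of the phosphate starvation list, 2 of 22 genes were called higher (12 adjusted over the list alone, adjusted p = 0.175 with an estimated correlation; 5 called without the low-rRNA libraries). These were the non-coding RNAs IPS1 (AT3G09922) and AT4 (AT5G03545), which rose by 2.59 ± 0.45 and 1.64 ± 0.26. Of 13 suberin genes 4 were called higher (5 adjusted over the list alone), among them FAR5 (AT3G44550) and the fatty acid hydroxylase CYP86A1 (AT5G58860) with 1.77 ± 0.23 and 1.97 ± 0.35. The other suberin genes were CYP86B1 (AT5G23190, 1.85 ± 0.35) and GPAT5 (AT3G11430, 1.96 ± 0.38), whose calls ended without 0 mM replicate 4 (adjusted p = 0.0595 and 0.0704), and that of GPAT5 also without 0 mM replicate 3 (0.0582). The iron transporter IRT1 (AT4G19690, chromosome 4, 10707344 to 10709015) fell from 161 ± 32.5 to 69.3 ± 3.99 CPM (−1.22 ± 0.18), and was 1 of 3 iron supply genes called lower, out of 17 (4 adjusted over the list alone). The other 2 were FIT1 (AT2G28160, −1.43 ± 0.32), whose call ended without any 1 of the 6 libraries (adjusted p = 0.0518 to 0.15), and FRO2 (AT1G01580, −0.98 ± 0.22), whose call ended in 5 of those fits, all but that without 0 mM replicate 3 (0.0705 to 0.154). Of 35 DNA damage response genes 2 were called higher (7 adjusted over the list alone, adjusted p = 0.229 with an estimated correlation), ERF115 and its paralogue ERF114 (AT5G61890, 3.08 ± 0.54). The cell cycle inhibitor SMR7 (AT3G27630, chromosome 3, 10230892 to 10231567) reached 1.93 in wild type without a call (adjusted p = 0.0637). Of 15 oxidative stress genes 2 were called higher (3 adjusted over the list alone, 0.156 with an estimated correlation), among them the glutathione transferase GSTF7 (AT1G02920, 1.79 ± 0.22). Root hair genes had negative log2 fold changes in 10 of 10 cases, 1 called (4 adjusted over the list alone, 0.128 with an estimated correlation).

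In als3-1, Al raised 16 of 35 DNA damage response genes (adjusted p = 0.126 for the list with an estimated correlation), and PLT1, PLT2 and AGP30 were among the genes it lowered. SMR7 rose from 0.535 ± 0.00748 to 13.9 ± 4.66 CPM (4.69 ± 0.49, adjusted p = 1.8e-05, n = 3 against 3) and the DNA repair gene XRI1 (AT5G48720) from 16.3 ± 1.91 to 86.9 ± 23.3 CPM (2.42 ± 0.25). BRCA1 (AT4G21070) of homologous recombination rose by 1.89 ± 0.24, and the poly(ADP-ribose) polymerases PARP1 (AT2G31320) and PARP2 (AT4G02390) by 1.04 ± 0.13 and 1.71 ± 0.28. The stem cell regulators PLT1 (AT3G20840) and PLT2 (AT1G51190) fell by 1.77 ± 0.25 and 1.14 ± 0.21, and AGP30 (AT2G33790), an arabinogalactan protein of roots, fell by 3.96 ± 0.27. Over all genes 2348 were called, 987 higher and 1361 lower, and 1152 of them changed at least 2-fold. The count was 4085 with the replicate block and 2102 without the low-rRNA libraries. It was 1539 without als3-1 0 mM replicate 2, and 1433 or 1362 without 1.5 mM replicate 2 or 3.

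Of the 35 DNA damage response genes, 16 were called higher in als3-1 and none lower (18 and 1 adjusted over the list alone), and 17 were higher without the low-rRNA libraries. ERF114 rose by 4.21 ± 0.46, RAD17 (AT5G66130) by 2.02 ± 0.28, the cohesin subunit SYN2 (AT5G40840) by 1.28 ± 0.21 and AGO2 (AT1G31280) by 0.87 ± 0.14. Beyond the list, the helicase gene AT1G20750 rose by 5.74 ± 0.56 and ABCA10 by 3.84 ± 0.32. Of 20 endocycle genes 2 were called higher and 2 lower (2 and 2 adjusted over the list alone, 1 lower without the low-rRNA libraries), and the higher were SMR7 and KRP6 (AT3G19150), another cell cycle inhibitor (0.68 ± 0.15). Of 23 G2/M genes 10 were called lower (15 adjusted over the list alone, 0.193 with an estimated correlation), among them the B-type cyclins CYCB1;3 (AT3G11520, −0.83 ± 0.13) and CYCB2;3 (AT1G20610, −0.72 ± 0.15). This fall went with a higher start: the mean log CPM of the list, centred over all libraries, was 0.226 to 0.318 in als3-1 and −0.4 to −0.132 in wild type at 0 mM. At 1.5 mM 0 of the 23 were called between als3-1 and wild type (median −0.09). Of 16 S phase genes 0 were called with edgeR (2 at unadjusted p under 0.05, 0 with DESeq2), and 0 were called with edgeR in the other 8 comparisons (0 to 3 at unadjusted p under 0.05, 0 or 1 with DESeq2).

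Of 20 stem cell niche and regeneration genes, 2 were called higher in als3-1, ERF115 and ERF114, and 5 lower (2 and 5 adjusted over the list alone). Besides PLT1 and PLT2, the phytosulfokine precursor gene PSK2 (AT2G22860) fell by 1.48 ± 0.33 and MGP (AT1G03840) by 0.64 ± 0.13. WOX5 (AT3G11260), the marker of the quiescent centre, was not called (−0.25), nor were SHR (AT4G37650, 0.18), SCR (AT3G54220, −0.11) and JKD (AT5G03150, 0.00). Of 5 root tissue genes 3 were called lower (3 adjusted over the list alone, 0.193 with an estimated correlation): the beta-glucosidases BGLU21 (AT1G66270, −1.07 ± 0.20) and BGLU22 (AT1G66280, −1.32 ± 0.26) and the aquaporin TIP2;3 (AT5G47450, −4.17 ± 0.61). Other large falls were those of GLR2.3 (−6.04 ± 0.60), the cellulose synthase-like gene ATCSLB05 (AT4G15290, −5.46 ± 0.50), the glyoxal oxidase-related gene AT1G19900 (−5.0 ± 0.36) and the lipid-transfer family genes AT5G46900 (−5.26 ± 0.78) and AT5G46890 (−4.67 ± 0.57). IRT1 fell from 108 ± 23.6 to 13.1 ± 1.58 CPM (−3.04 ± 0.19), with FIT1 (−2.21 ± 0.33) and FRO2 (−1.52 ± 0.23), the 3 of 17 iron supply genes called lower (4 adjusted over the list alone). CYP82C4 (AT4G31940) of coumarin synthesis fell by 4.12 ± 0.96, and its call (adjusted p = 0.0112) ended without 0 mM replicate 4 or 1.5 mM replicate 2 or 3 (0.0505 to 0.0596).

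ALMT1 rose in als3-1 from 69.5 ± 9.67 to 158 ± 13.4 CPM (1.18 ± 0.18), MATE by 1.67 ± 0.23 and PGIP2 (AT5G06870) by 1.26 ± 0.21, as members of the aluminium resistance list, of which 11 of 19 genes were called higher and 2 lower (the same adjusted over the list alone, and 9 and 0 without the low-rRNA libraries). HAK5 rose by 3.27 ± 0.32. Of 13 suberin genes 6 were called higher (6 higher and 2 lower adjusted over the list alone, 0.0643 with an estimated correlation), with CYP86A1 at 3.45 ± 0.36, CYP86B1 at 3.0 ± 0.36, FAR5 at 2.03 ± 0.23 and FAR4 (AT3G44540) at 1.66 ± 0.22. Of 22 phosphate starvation genes 14 were called higher (16 adjusted over the list alone, 0.135 with an estimated correlation), among them IPS1 (2.84 ± 0.47), AT4 (2.24 ± 0.26) and the phospholipase NPC4 (AT3G03530, 1.51 ± 0.24). Of 15 oxidative stress genes 3 were called higher (3 adjusted over the list alone, 0.0643 with an estimated correlation), with GSTF7 at 1.54 ± 0.22 and GSTU24 (AT1G17170) at 1.33 ± 0.27.

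Members of the defence and seed lists also rose in als3-1, with large spread between the libraries. The mean log CPM of the defence list, centred over all libraries, was 2.102, 1.512 and −0.513 in als3-1 1.5 mM replicates 2, 3 and 4. It rose in wild type too, where it lay between −0.969 and −0.033 at 0 mM and between 0.724 and 1.571 at 1.5 mM. In wild type 5 of 12 defence genes had an unadjusted p under 0.05, and 1 was higher with DESeq2. In als3-1, 7 of 12 defence genes were called higher (7 adjusted over the list alone, 0.193 with an estimated correlation, 4 called without the low-rRNA libraries), and PAD3 (AT3G26830) of camalexin synthesis rose by 1.29 ± 0.23. CYP71A13 (AT2G30770) of the same pathway rose by 8.20 ± 1.66, with 38.3, 6.38 and 0.121 CPM in 1.5 mM replicates 2, 3 and 4. Of 15 seed protein genes 6 were called higher (10 adjusted over the list alone, 0.352 with an estimated correlation), and the embryogenesis gene EM6 (AT2G40170) rose by 4.46 ± 0.84, with 5.42, 9.72 and 0.304 CPM in the same 3 libraries. Of 9 abscisic acid genes 2 were called higher and 1 lower (2 and 1 adjusted over the list alone, 0.556 with an estimated correlation), and RD29B (AT5G52300) rose by 2.90 ± 0.62. ARCK1 (AT4G11890), a receptor-like kinase, rose by 3.41 ± 0.89, and its call (adjusted p = 0.0217) ended without 0 mM replicate 2, 3 or 4 or 1.5 mM replicate 2 (0.0722 to 0.117). The seed list had a positive median in sog1-7 too (2.43), with 0 of 15 genes called with edgeR (8 at unadjusted p under 0.05, 4 with DESeq2, 6 adjusted over the list alone).

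**Figure D2:**
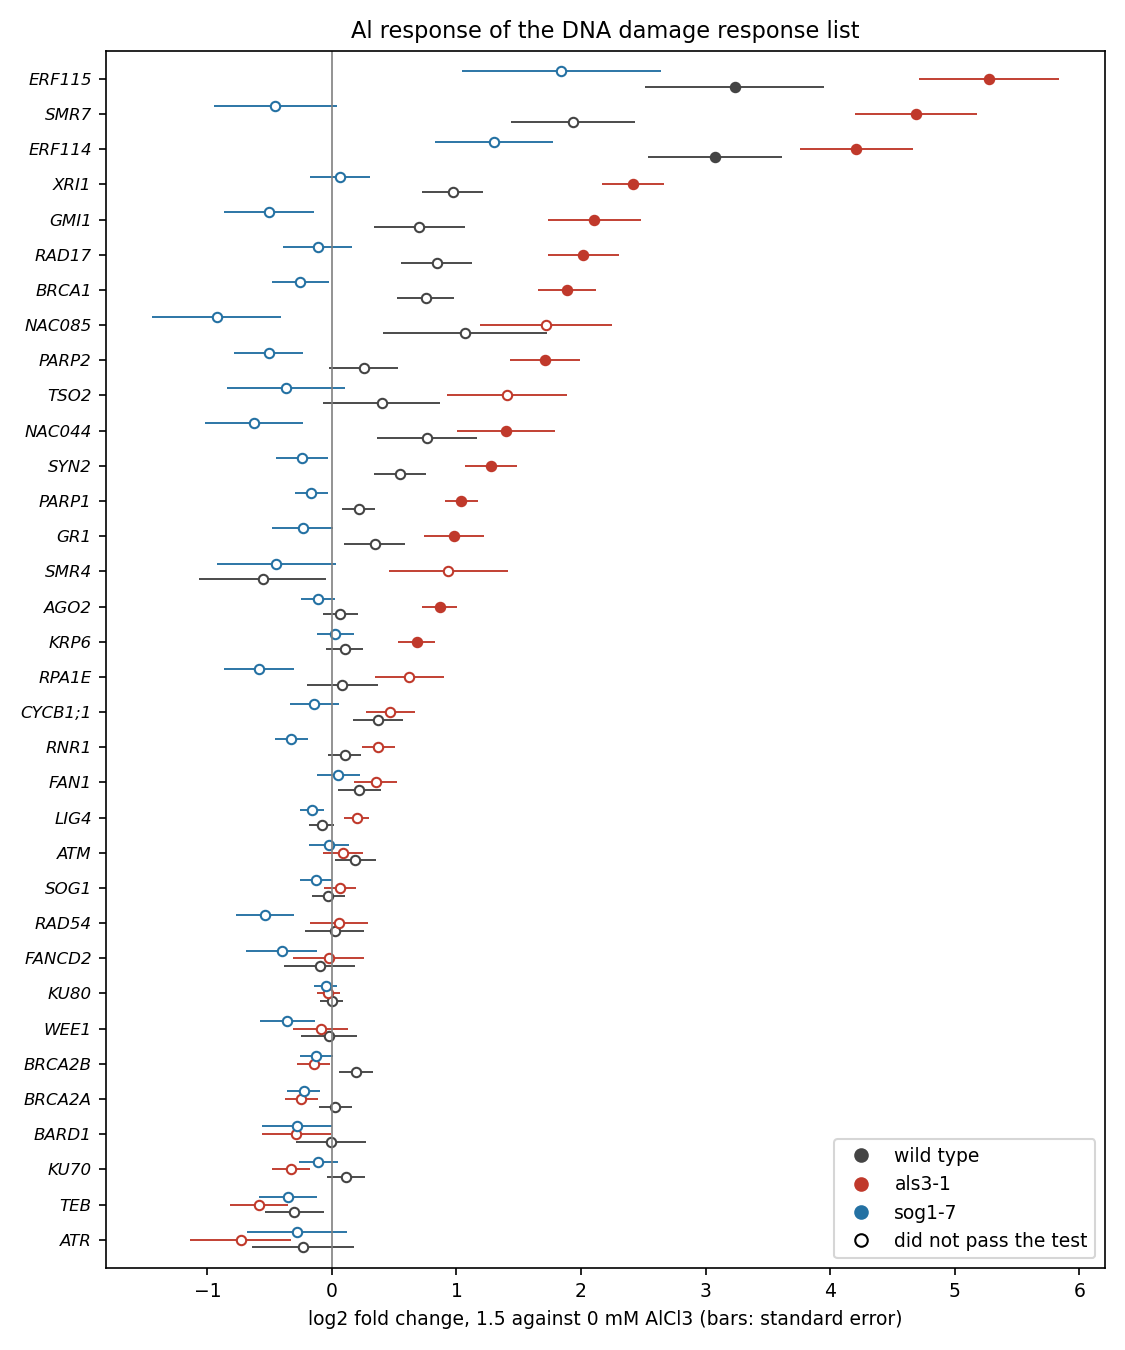
Log2 fold change ± SE of 34 of the 35 DNA damage response genes between 1.5 and 0 mM AlCl3 in wild type, als3-1 and sog1-7. Filled points passed an adjusted p of 0.05 over all genes.

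In sog1-7, Al raised ALMT1 from 9.76 ± 2.26 to 131 ± 7.4 CPM (3.74 ± 0.20, adjusted p = 7.32e-08, n = 3 against 3), while no DNA damage response gene was called. HAK5 rose by 3.90 ± 0.35, TIL2 by 3.69 ± 0.31, AT2G43590 by 3.54 ± 0.19, the phosphatase gene PEPC1 (AT1G17710) by 2.44 ± 0.37 and CBSX5 (AT4G27460) by 2.40 ± 0.39. IRT1 fell from 44.6 ± 7.56 to 5.29 ± 0.669 CPM (−3.08 ± 0.19) and the ferric reductase FRO2 from 22.2 ± 5.41 to 4.99 ± 0.209 CPM (−2.15 ± 0.24). GLR2.3, WAK4, SULTR1;1 and the stachyose synthase STS (AT4G01970) fell by 4.04 ± 0.50, 2.90 ± 0.36, 2.79 ± 0.42 and 2.3 ± 0.28, and AT1G29090 fell by 2.27 ± 0.37 (0.105 without the low-rRNA libraries, 1.05e-07 to 0.105 over all alternatives). Over all genes 257 were called, 160 higher and 97 lower, and 187 of them changed at least 2-fold. On the FPKM scale 145 were higher and 49 lower. The count was 573 with the replicate block and 143 without the low-rRNA libraries. It was 162 or 167 without sog1-7 0 mM replicate 2 or 3, and 144 without 1.5 mM replicate 4.

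Of the 35 DNA damage response genes 0 were called in sog1-7 with edgeR (4 at unadjusted p under 0.05, 0 with DESeq2), 29 had negative log2 fold changes, and SMR7 had −0.45. Of 19 aluminium resistance genes 7 were called higher (10 higher and 2 lower adjusted over the list alone), with MATE at 2.15 ± 0.24 and GDH1 at 1.44 ± 0.14. Of 22 phosphate starvation genes 5 were called higher (13 adjusted over the list alone, adjusted p = 0.06 with an estimated correlation and 0.0243 without the low-rRNA libraries), with IPS1 at 2.74 ± 0.46, AT4 at 1.92 ± 0.26 and NPC4 at 1.58 ± 0.25. The purple acid phosphatase PAP14 (AT2G46880) rose by 3.95 ± 0.78, and its call (adjusted p = 0.0167) ended without 0 mM replicate 2, 3 or 4 or 1.5 mM replicate 3 (0.0635 to 0.092). Of 13 suberin genes 4 were called higher (4 adjusted over the list alone, 1 called without the low-rRNA libraries), and the list passed with an estimated correlation (0.0121), but not without those libraries (0.153). FAR5 rose by 1.48 ± 0.23. Of 17 iron supply genes 3 were called lower (4 adjusted over the list alone, 0.06 with an estimated correlation), IRT1, FRO2 and FIT1, and the call of FIT1 (−1.62 ± 0.32) ended without 0 mM replicate 2 or 1.5 mM replicate 3 or 4 (0.0941 to 0.114).

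The Al responses of the 3 genotypes shared 146 genes, 78 higher and 68 lower, among them ALMT1, MATE, HAK5, IPS1, AT4, FAR5, GLR2.3 and IRT1. Wild type and als3-1 shared 134 genes called higher and 158 lower, where independent lists would share 8.84 and 13.5. The same numbers were 112 and 81 against 7.29 and 6.10 for als3-1 and sog1-7, and 104 and 79 against 1.43 and 0.959 for wild type and sog1-7. The opposite direction was called for 1 gene between wild type and als3-1 and for 1 gene between als3-1 and sog1-7. With the replicate block the shared counts of 292, 193, 183 and 146 were 595, 411, 351 and 288. Without the low-rRNA libraries the first 3 were 321, 125 and 118. The 292 became 186, 186 or 167 without wild type 0 mM replicate 3, 0 mM replicate 4 or 1.5 mM replicate 4, and the 193 and 183 both became 119 without sog1-7 1.5 mM replicate 4.

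The Al response differed between als3-1 and sog1-7 most for SMR7 among the DNA damage response genes (difference 5.14 ± 0.68 log2 units, adjusted p = 0.00118, n = 3 in each of 4 groups). XRI1 differed by 2.35 ± 0.34, BRCA1 by 2.14 ± 0.33 and PARP1 by 1.2 ± 0.18, and TRFL10 (AT5G03780), a telomere-repeat-binding-factor-like gene, by 2.46 ± 0.33. ALMT1 differed by −2.56 ± 0.26, ATCSLB05 by −4.64 ± 0.62, AT1G19900 by −3.88 ± 0.45 and BGLU22 by −2.06 ± 0.37. At 0 mM ALMT1 had 60.6 to 79.8 CPM in als3-1 and 7.18 to 11.4 CPM in sog1-7. At 1.5 mM it had 144 to 170 and 122 to 135 CPM, so its smaller rise in als3-1 went with a higher start and not with a lower end. The glycoside hydrolase gene AT2G16230 differed by −3.38 ± 0.43, the desaturase family gene AT1G06120 by −3.18 ± 0.37 and AT5G46900 and AT5G46890 by −5.56 ± 0.96 and −4.79 ± 0.71. Over all genes 249 differences were called, 60 higher and 189 lower. The count was 411 with the replicate block and 109 without the low-rRNA libraries, and it was 149 without als3-1 1.5 mM replicate 3.

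Of the 35 DNA damage response genes 11 were called higher in this difference (20 adjusted over the list alone, 5 without the low-rRNA libraries), and the list passed with an estimated correlation (adjusted p = 0.0389), but not without the low-rRNA libraries (0.0816). RAD17 differed by 2.13 ± 0.39 and PARP2 by 2.22 ± 0.39, and their calls ended without the low-rRNA libraries (0.0816 and 0.0842; over all alternatives 3.2e-05 to 0.0816 and 1.12e-05 to 0.0842). GMI1 (AT5G24280) differed by 2.61 ± 0.52 (adjusted p = 0.0191), and its call ended without als3-1 0 mM replicate 2, 3 or 4, als3-1 1.5 mM replicate 3 or sog1-7 1.5 mM replicate 2 or 3 (0.0526 to 0.0627). The call of AT1G20750 (5.31 ± 0.95) ended without sog1-7 0 mM replicate 4 (0.0501), and that of SYN2 (1.51 ± 0.29) without als3-1 0 mM replicate 3 or 4 or 1.5 mM replicate 3 (0.0518 to 0.0531). PLT1 differed by −1.74 ± 0.35 (adjusted p = 0.0189), and its call ended without als3-1 0 mM replicate 2 or 3, als3-1 1.5 mM replicate 2 or 3 or sog1-7 1.5 mM replicate 4 (0.05 to 0.0644). ABCA10 differed by 3.11 ± 0.48 (0.0816 without the low-rRNA libraries, 8.19e-08 to 0.0816 over all alternatives). Of the root tissue genes 2 of 5 were called lower (3 adjusted over the list alone, 0.213 with an estimated correlation), and of the stem cell niche genes 1 of 20 was called higher and 2 lower (2 and 5 adjusted over the list alone). Without the low-rRNA libraries 1 root tissue gene and 0 stem cell niche genes were called.

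Of the genes called in als3-1, 60 rose and rose more than in sog1-7, and 172 fell and fell more than in sog1-7. The 60 held 11 DNA damage response genes, with SMR7, XRI1, BRCA1 and PARP1 among them. Their median log2 fold change was 1.71 in als3-1, 0.547 in wild type and −0.158 in sog1-7, and 7 were also called higher in wild type and 1 in sog1-7. The 172 had medians of −1.75, −0.315 and 0.00509, and 27 were also called lower in wild type and 4 in sog1-7. With the replicate block the 2 sets held 111 and 273 genes, and without the low-rRNA libraries 24 and 79. The first set held 37, 38 or 37 genes without als3-1 0 mM replicate 2, 3 or 4, 28 without als3-1 1.5 mM replicate 3, 36 without sog1-7 0 mM replicate 4 and 36 or 34 without sog1-7 1.5 mM replicate 3 or 4. The second held 113 without als3-1 1.5 mM replicate 3.

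Between als3-1 and wild type, the Al response differed for ALMT1 by −2.53 ± 0.26 (adjusted p = 0.000986, n = 3 in each of 4 groups) and for IRT1 by −1.82 ± 0.25 (adjusted p = 0.00398). ALMT1 had 60.6 to 79.8 CPM in als3-1 and 7.52 to 11.9 CPM in wild type at 0 mM, and 144 to 170 and 116 to 144 CPM at 1.5 mM. ATCSLB05 differed by −4.57 ± 0.62, AT1G19900 by −3.46 ± 0.45 and the terpene synthase TPS30 (AT3G32030) by −3.05 ± 0.46. The F-box gene AT5G07610 differed by 1.67 ± 0.29 (0.0602 without wild type 0 mM replicate 3), and the auxin-conjugating enzyme BRU6 (AT4G37390) by 1.27 ± 0.22. The call of BRU6 (adjusted p = 0.0182) ended without wild type 0 mM replicate 2 or 3, wild type 1.5 mM replicate 2 or 3 or als3-1 1.5 mM replicate 3 (0.0561 to 0.0674). AT5G46890 differed by −4.38 ± 0.72 (0.054 without als3-1 1.5 mM replicate 2). MAKR4 (AT2G39370) of root development differed by 1.39 ± 0.24 (adjusted p = 0.0159), and its call ended without wild type 0 mM replicate 3 or 4, wild type 1.5 mM replicate 2 or 3, als3-1 0 mM replicate 4 or als3-1 1.5 mM replicate 2 (0.05 to 0.0629). GEX1 (AT5G55490), a gamete-expressed gene, differed by 1.67 ± 0.34 (adjusted p = 0.0448), and its call ended in 10 of 12 such fits, all but those without als3-1 0 mM replicate 2 and als3-1 1.5 mM replicate 4 (0.0561 to 0.174). The threonine aldolase THA1 (AT1G08630) differed by 1.33 ± 0.27 (adjusted p = 0.0484), and its call ended without any 1 of the 12 libraries (0.069 to 0.174). No member of the DNA damage list was called with edgeR (12 at unadjusted p under 0.05, 6 with DESeq2, 8 adjusted over the list alone, 0.373 with an estimated correlation). Over all genes 87 were called, 7 higher and 80 lower, and on the FPKM scale 7 higher and 9 lower. The count was 151 with the replicate block and 68 without the low-rRNA libraries. It was 55 or 34 without wild type 0 mM replicate 2 or 3, 49 or 41 without wild type 1.5 mM replicate 2 or 3, 52 without als3-1 0 mM replicate 3 and 42 or 49 without als3-1 1.5 mM replicate 2 or 3.

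Between sog1-7 and wild type, the Al response differed for 1 gene, IRT1 (−1.86 ± 0.26, adjusted p = 0.0482, n = 3 in each of 4 groups), and its call ended without any 1 of the 12 libraries (0.0711 to 0.218). At unadjusted p under 0.05 there were 435 genes, and the count was 4 with the replicate block, 3 with DESeq2 and 0 without the low-rRNA libraries. Of the 35 DNA damage response genes 34 had negative differences, and the list passed with an estimated correlation (adjusted p = 0.0448, 0.13 with fry) without a called member (0 with edgeR, 10 at unadjusted p under 0.05, 0 with DESeq2). Without the low-rRNA libraries it did not pass (0.226, 0.369 with fry). Of 17 iron supply genes 1 was called lower (1 higher and 4 lower adjusted over the list alone, 0 called without the low-rRNA libraries), and that list passed too (0.0448 with an estimated correlation, 0.13 with fry), but not without the low-rRNA libraries (0.226 and 0.369). The 16 S phase genes all had negative differences (0.392 with an estimated correlation).

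**Figure D3:**
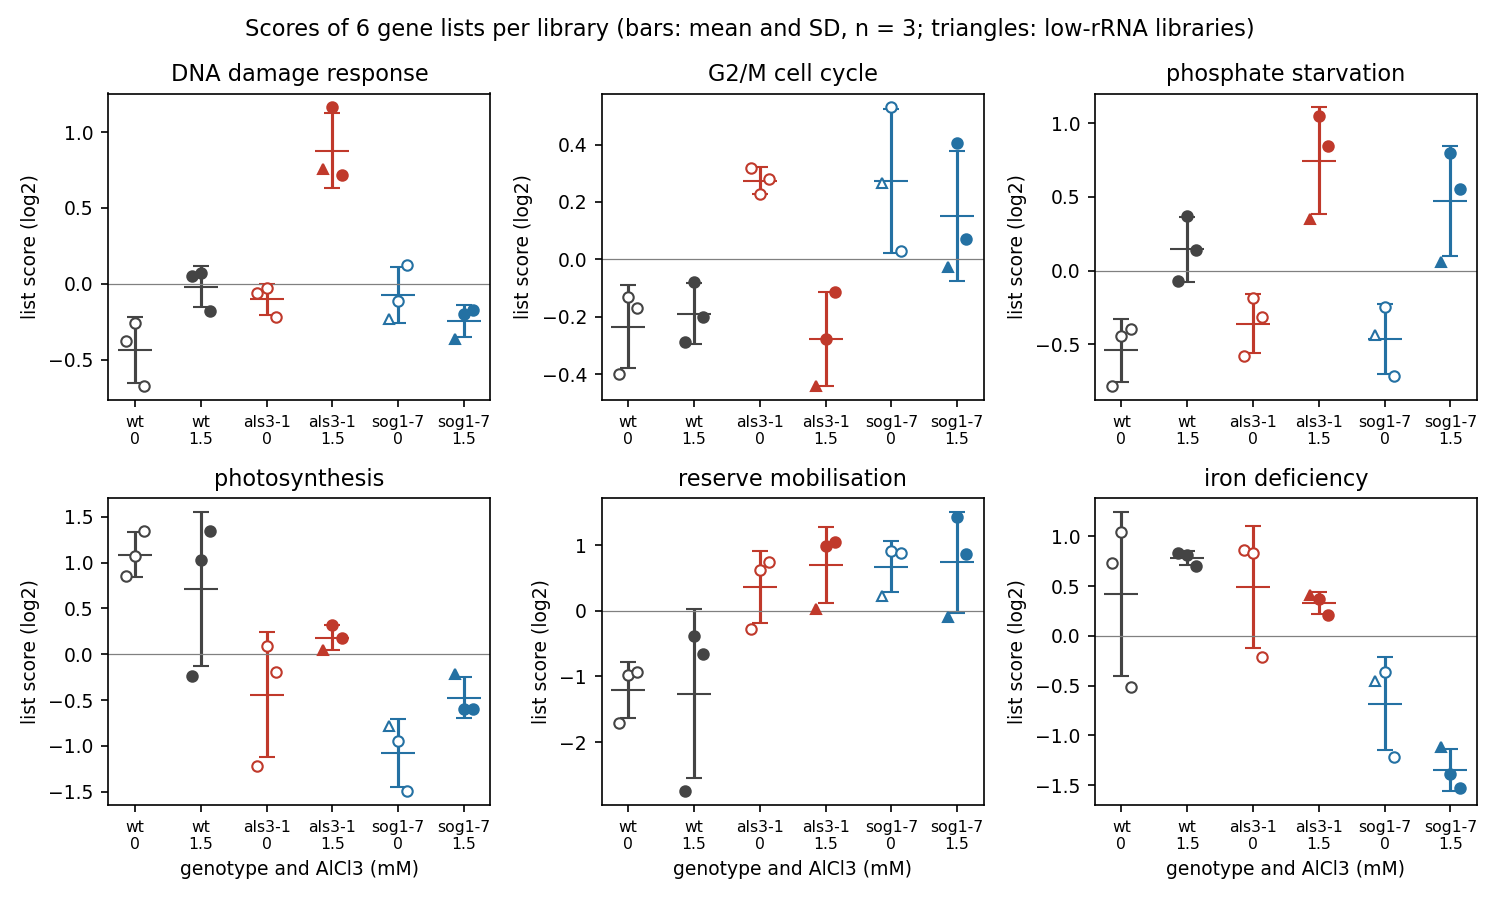
Score of 6 gene lists in each library, the mean log CPM of the list members centred over all libraries, for the DNA damage response, G2/M phase, phosphate starvation, photosynthesis, seed reserves and iron supply.

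At 1.5 mM, als3-1 and sog1-7 differed in members of the DNA damage response, iron supply and root lists. SMR7 was higher in als3-1 by 4.78 ± 0.49 (0.493 ± 0.212 CPM in sog1-7, 13.9 ± 4.66 CPM in als3-1, adjusted p = 2.84e-05, n = 3 against 3), XRI1 by 2.62 ± 0.25, BRCA1 by 2.22 ± 0.24 and the ribonucleotide reductase subunit TSO2 (AT3G27060) by 2.66 ± 0.50. FRO2 was higher by 2.58 ± 0.24 and IRT1 by 1.31 ± 0.19. PLT1 was lower in als3-1 by 1.97 ± 0.25, and CYCB1;3 by 0.91 ± 0.13. QQS (AT3G30720), a regulator of starch content, had 0.19 ± 0.179 CPM in als3-1 and 36.1 ± 15.3 CPM in sog1-7 (−7.43 ± 0.51). Over all genes 1448 were called, 588 higher and 860 lower in als3-1, 664 of them at least 2-fold, and on the FPKM scale 257 were higher and 613 lower. The count was 3136 with the replicate block and 952 without the low-rRNA libraries. It was 790 or 661 without als3-1 replicate 2 or 3, and 767 or 639 without sog1-7 replicate 3 or 4.

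Of the 35 DNA damage response genes 17 were higher in als3-1 at 1.5 mM (21 adjusted over the list alone, adjusted p = 0.0436 with an estimated correlation and 0.151 without the low-rRNA libraries). AT1G20750 was higher by 6.13 ± 0.57, ABCA10 by 4.14 ± 0.32, the MYB-like gene ASG4 (AT1G01520) by 4.13 ± 0.84 and ERF114 by 2.96 ± 0.41. Of 17 iron supply genes 8 were higher (12 higher and 2 lower adjusted over the list alone, 0.0436 with an estimated correlation). Without the low-rRNA libraries 4 were higher and the list did not pass (0.151). Among the 8 were the transcription factors MYB72 (AT1G56160, 4.93 ± 0.87) and MYB10 (AT3G12820, 1.35 ± 0.21). The iron deficiency regulator BHLH100 (AT2G41240) was higher by 4.56 ± 1.29, and its call (adjusted p = 0.0452) ended without als3-1 replicate 2 or 3 or sog1-7 replicate 3 or 4 (0.0992 to 0.164). Of 5 root tissue genes 3 were lower in als3-1 (3 adjusted over the list alone, 0.258 with an estimated correlation), TIP2;3 by 3.29 ± 0.61, BGLU22 by 1.89 ± 0.27 and BGLU21 by 1.28 ± 0.20. Also lower in als3-1 were ATCSLB05 (−4.85 ± 0.50), AT5G46900 (−6.78 ± 0.79), AT5G46890 (−5.64 ± 0.58), AT1G19900 (−3.94 ± 0.35) and AT2G16230 (−3.31 ± 0.33), and the pectin lyase-like gene AT1G05660 (−3.20 ± 0.43). Of 20 stem cell niche genes 3 were higher and 4 lower (3 and 5 adjusted over the list alone), and 3 of 23 G2/M genes were lower (12 adjusted over the list alone, 0.285 with an estimated correlation, 1 called without the low-rRNA libraries). Against wild type at 1.5 mM, 3 of the 23 G2/M genes were higher in sog1-7 (median 0.38, 0.35 with an estimated correlation) and 0 were called in als3-1 (median −0.09). Of 12 defence genes 3 were higher (8 adjusted over the list alone, 0.258 with an estimated correlation, 1 called without the low-rRNA libraries), with PAD3 at 1.78 ± 0.24. In the added contrasts with wild type at 1.5 mM, 3 defence genes were lower in sog1-7 (median of the list −2.04). In als3-1 2 were higher (median 0.65), and neither list passed with an estimated correlation (adjusted p = 0.348 and 0.822).

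At 0 mM, als3-1 had more ALMT1 transcript than wild type (69.5 ± 9.67 against 10.1 ± 2.29 CPM, 2.78 ± 0.19, adjusted p = 4.48e-06, n = 3 against 3). GSTF7 was higher by 1.26 ± 0.22 and GDH1 by 0.85 ± 0.14. The light-harvesting gene LHCB2.3 (AT3G27690) had 37.4 ± 15.6 CPM in als3-1 and 450 ± 109 CPM in wild type (−3.59 ± 0.61). The B-box gene BBX16 (AT1G73870) was lower by 5.28 ± 0.83 and the protein kinase CIPK20 (AT5G45820) by 4.38 ± 0.47. MYB15 (AT3G23250) was higher by 3.10 ± 0.70 and LEA4-5 (AT5G06760), a late embryogenesis abundant gene, by 3.15 ± 0.73. The call of MYB15 (adjusted p = 0.0314) ended without wild type replicate 2, 3 or 4 or als3-1 replicate 4 (0.0881 to 0.137), and that of LEA4-5 (0.0363) without those 4 or als3-1 replicate 3 (0.0881 to 0.127). Over all genes 502 were called, 185 higher and 317 lower, 251 of them at least 2-fold, and on the FPKM scale 189 were higher and 66 lower. The count was 1595 with the replicate block and 1027 without the low-rRNA libraries, none of which was in these 2 groups. It was 173 or 190 without wild type replicate 3 or 4, and 237, 244 or 154 without als3-1 replicate 2, 3 or 4.

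Of 14 photosynthesis genes 3 were lower in als3-1 at 0 mM (13 adjusted over the list alone, adjusted p = 0.139 with an estimated correlation), and of 23 G2/M genes 4 were higher (15 adjusted over the list alone, 0.141 with an estimated correlation). The aluminium resistance list had 2 of 19 genes higher, ALMT1 and GDH1 (4 higher and 2 lower adjusted over the list alone, 0.224 with an estimated correlation). The DNA damage response list had 33 of 35 positive log2 fold changes and 0 called with edgeR (7 at unadjusted p under 0.05, 0 with DESeq2, 0.224 with an estimated correlation, 1 called without the low-rRNA libraries). The 12 xylem genes all had negative log2 fold changes, with 0 called with edgeR (5 at unadjusted p under 0.05, 0 with DESeq2, 0.11 with an estimated correlation).

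At 0 mM, 12 of 14 photosynthesis genes and 5 of 17 iron supply genes were lower in sog1-7 than in wild type (adjusted p = 0.0726 and 0.107 with an estimated correlation). The small Rubisco subunit gene RBCS2B (AT5G38420) had 333 ± 159 CPM in sog1-7 and 3760 ± 527 CPM in wild type (−3.50 ± 0.41, adjusted p = 0.000206, n = 3 against 3). LHCB2.3 was lower by 4.92 ± 0.65, LHB1B1 (AT2G34430), another light-harvesting gene, by 4.03 ± 0.87 and LHCA1 (AT3G54890) of photosystem I by 3.08 ± 0.43. FRO2 was lower by 2.65 ± 0.24 (140 ± 30.3 to 22.2 ± 5.41 CPM) and IRT1 by 1.85 ± 0.18. BBX16, CIPK20 and CYP82C4 were lower by 5.26 ± 0.82, 4.39 ± 0.47 and 4.61 ± 0.93. QQS was higher by 4.96 ± 0.43 and MYB15 by 3.17 ± 0.70, and ABI4 (AT2G40220), a transcription factor of abscisic acid signalling, by 2.96 ± 0.75 (0.0642 without sog1-7 replicate 3). Over all genes 2211 were called, 1146 higher and 1065 lower, 774 of them at least 2-fold, and on the FPKM scale 1570 were higher and 299 lower. The count was 2778 without the low-rRNA libraries. It was 1446 or 1208 without wild type replicate 2 or 3, and 1313 or 1370 without sog1-7 replicate 3 or 4.

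The 12 photosynthesis genes lower in sog1-7 at 0 mM (14 adjusted over the list alone) held PRK (AT1G32060, −1.52 ± 0.21) and GAPA1 (AT3G26650, −1.25 ± 0.21) of the Calvin cycle. Of 3 reserve mobilisation genes 2 were higher (3 adjusted over the list alone, 0.238 with an estimated correlation). They were the malate synthase MLS (AT5G03860, 2.21 ± 0.57, adjusted p = 0.0217) and PCK1 (AT4G37870, 1.41 ± 0.36, adjusted p = 0.0205), and both calls ended without wild type replicate 2 or 3 or sog1-7 replicate 3 or 4 (0.0529 to 0.0893). The 5 iron supply genes that were lower (9 adjusted over the list alone) held MYB10 at −1.19 ± 0.21. Of 23 G2/M genes 8 were higher (16 adjusted over the list alone, 0.178 with an estimated correlation), with CYCB1;3 at 0.85 ± 0.13 and CYCB1;2 (AT5G06150) at 0.60 ± 0.13. Of 16 ethylene and auxin genes 3 were lower (5 adjusted over the list alone, 0.0726 with an estimated correlation), with the auxin response genes IAA29 (AT4G32280, −3.38 ± 0.65) and IAA19 (AT3G15540, −1.60 ± 0.28). Of 6 heat shock genes 1 was higher, HSP90.1 (AT5G52640, 0.92 ± 0.19; 2 adjusted over the list alone, 0.238 with an estimated correlation, 2 called without the low-rRNA libraries). Of 35 DNA damage response genes 3 were higher (3 adjusted over the list alone, 0.299 with an estimated correlation, 8 called without the low-rRNA libraries), with NAC085 (AT5G14490) at 2.97 ± 0.62.

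The first 3 principal components of the 18 libraries held 24.5%, 19.6% and 13.7% of the variance. On the last of these the 3 low-rRNA libraries lay at −40.7, −57.2 and −55.8 and the other 15 between −14.7 and 34.7. A term for the low-rRNA libraries passed for 7953 of 21650 genes, 889 of them at least 2-fold. The low-rRNA libraries were 1 of 3 libraries in als3-1 at 1.5 mM and in both sog1-7 groups, so they lie across the Al response of als3-1 and across sog1-7 against wild type.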

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

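The Al response differed between genotypes by a test of the difference itself, which was planned, while the tests of explanations and the splits of the libraries below were chosen after the results were seen. Between als3-1 and sog1-7 249 genes differed, and 60 genes were raised in als3-1 and raised more than in sog1-7, with 172 in the mirror set. SMR7 differed by 5.14, TRFL10 by 2.46, XRI1 by 2.35, BRCA1 by 2.14 and PARP1 by 1.2 log2 units. ATCSLB05 differed by −4.64, AT1G19900 by −3.88, ALMT1 by −2.56, BGLU22 by −2.06 and PLT1 by −1.74. ALMT1 rose with Al in als3-1 too, from a higher level without Al than in sog1-7 or wild type. Between als3-1 and wild type 87 genes differed, with ATCSLB05 at −4.57, AT1G19900 at −3.46, ALMT1 at −2.53 and IRT1 at −1.82. Between sog1-7 and wild type 1 gene differed, IRT1 at −1.86.

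Of 35 DNA damage response genes 16 rose with Al in als3-1 (adjusted p = 0.126 for the list with an estimated correlation) and 11 rose more there than in sog1-7 (0.0389, and 0.0816 without the low-rRNA libraries). The difference had a median of 0.98 (median SE 0.33) over all 35 list members and 2.14 over the 11 called. Without the 3 low-rRNA libraries the median over the 35 was 0.80 (median SE of single genes 0.37) and 32 were positive. The difference of the mean list scores was 1.23 without them (SE over libraries 0.26), which argues against these libraries as the whole source. The median over the 11 was 2.33 without them, all 11 stayed positive, and 5 stayed called as the median SE went from 0.34 to 0.42 with fewer libraries. The 11 were picked by this same difference, so their values cannot decide about the low-rRNA libraries. A smaller share of root tissue in als3-1 at 1.5 mM would raise green-tissue transcripts by about as much. The mean score of the list differed by 1.15 (SE 0.20) and that of the photosynthesis list by 0.02 (SE 0.48). The gap between them was 1.13 (SE 0.56), and 1.16 (SE 0.59) without the low-rRNA libraries. Within replicates 2, 3 and 4 it was 0.25, 1.39 and 1.76 (SE 0.45, 95% interval −0.82 to 3.09), and with the replicate block in a fit of all libraries 1.13 (SE 0.68), or 1.52 (SE 0.56) without the low-rRNA libraries. Some of these gaps exceed 2 SE and others do not, so a smaller share cannot be told apart from a change in these genes with so few libraries. Of 100 splits of the 12 libraries 6 called as many list members as the real 11 (highest other 13, and 11 among the 20 splits that part as many pairs). The 5 others among these kept the 3 libraries of 1 genotype at 1 dose together and so carry the difference of the genotypes, and the highest of the 79 splits that did not was 0, so these splits leave chance undecided. The genotype sog1-7, which the design names, stays open as an untested biological explanation, as does a difference in Al damage that does not depend on SOG1.

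Of 5 root markers 3 fell with Al in als3-1 (adjusted p = 0.193 for the list with an estimated correlation), and the median over all 5 was −1.07 (median SE 0.24). Without the low-rRNA libraries the median was −1.09 (median SE of single genes 0.21) and all 3 stayed called. The root list score was −0.984 and −0.714 in als3-1 1.5 mM replicates 3 and 4, and 0.061 to 0.397 in als3-1 at 0 mM, which argues against the low-rRNA libraries as the whole source. The summed reads of the near-identical BGLU21 and BGLU22 fell by 1.15 (−1.15, SE 0.20), which argues against reads moving between the 2 copies. A smaller share of root tissue as the whole cause would lower the 5 markers alike only if all were equally confined to the root. That was not checked in these whole seedlings. Their changes ran from −4.17 ± 0.61 for TIP2;3 to 0.12 ± 0.24 for BGLU23 (AT3G09260), with −0.19 ± 0.17 for NAI2 (AT3G15950). They spread around a common value by a chi-square of 61.1 (4 degrees of freedom, p = 1.74e-12), so the 5 did not fall alike. Markers that differ in how far they are confined to the root would spread too, so the chi-square cannot decide the question. A smaller share, as the whole cause or as part of it, stays open. The photosynthesis list went the way a smaller share would move it, with 13 of 14 members positive in als3-1 and a median of 0.54 (adjusted p = 0.0167 with the preset correlation, 0.551 with an estimated one, 0 called with edgeR, 0 at unadjusted p under 0.05 and 0 with DESeq2). In sog1-7 the median was 0.57 with 14 of 14 positive. Damage of the root in als3-1 by Al, the biology that the design names, is a hypothesis here.

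Of 14 photosynthesis genes 12 were lower in sog1-7 and 3 in als3-1 than in wild type at 0 mM (adjusted p = 0.0726 and 0.139 for the list with an estimated correlation), with list score differences of −2.16 (SE 0.26) in sog1-7 and −1.53 (SE 0.42) in als3-1. Without the low-rRNA library of sog1-7 the first was −2.31 (SE 0.31), which argues against that library as the source. Wild-type libraries shared by both comparisons and high by chance were weighed with the separate libraries at 1.5 mM, where sog1-7 differed by −1.19 (SE 0.50) and als3-1 by −0.53 (SE 0.49). Within replicates 2, 3 and 4 sog1-7 differed by 0.02, −1.63 and −1.94 (SE 0.61) and als3-1 by 0.28, −0.71 and −1.16 (SE 0.43). Not all of these exceed 2 SE, so such libraries and the genotype cannot be told apart. Less advanced seedlings in the mutants cannot be told apart from the genotype itself either, because age was not measured and the 3 reserve transcripts had a median of 2.01 in sog1-7, with 2 of 3 called there and 0 of 3 in als3-1 (3 of 3 at unadjusted p under 0.05 and 2 with DESeq2).

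Other splits of the same libraries gave as many genes for the tested differences. For als3-1 against sog1-7, 5 of 100 splits of the 12 libraries gave at least 249 genes (highest other 490, and 360 among the 20 splits that part as many pairs), 5 gave at least the 60 raised genes (190 and 84) and 5 at least the 172 lowered genes (265 and 265). For als3-1 against wild type 6 of 100 gave at least 87 (159 and 159), and for sog1-7 against wild type 8 of 100 gave at least 1 (943 and 5). Each of the other splits as large kept the 3 libraries of 1 genotype at 1 dose together, as 20 of the 99 other splits did, so the 943 and the 490 point to a structure of the samples, the difference of the genotypes at 1 dose. The highest of the 79 splits without such a group was 0 in each case, so these splits leave chance undecided.

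For the comparisons of 2 groups, 10 splits are too few for a share under 0.05, and 1 split, the real one, was as large in each. The highest other split called 0 genes against 408, 2348 and 257 in the Al responses of wild type, als3-1 and sog1-7, 2211 in sog1-7 against wild type at 0 mM, and 1207 and 1602 in als3-1 and sog1-7 against wild type at 1.5 mM. It called 3 genes against 1448 in als3-1 against sog1-7 at 1.5 mM and 3 against 502 in als3-1 against wild type at 0 mM. For the genes shared by the Al responses, 292, 193, 183 and 146, 1 of 100 splits was as large, the real one, and the highest other shared 0 genes. The other splits of each response alone called 0 genes, which fixes their shared count at 0, and only 10 others part as many pairs as the real one, too few for a share under 0.05, so nothing about chance follows from these counts.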

How the results depend on the processing

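The alternatives without the low-rRNA libraries or with a term for them, and the mutants against wild type at 1.5 mM, were chosen after the results were seen, and the other alternatives were planned. Of 338 called values of the genes selected by the rule or for the added contrasts, none reversed in any alternative. The replicate block and DESeq2 kept all 338 calls, the scaling with DESeq2 size factors kept 337, no filter on low counts 322, the low-rRNA term 335 and that term with the block 335. The limma test on log2(FPKM + 1) kept 252, the fits without the low-rRNA libraries 274 and the fits of only the groups compared 240 of 335. Over the fits without 1 library 1835 of 2334 values kept their call. A minimum change of 2-fold calls fewer genes by construction, and for the other changes below the cause was not tested. The power to see small changes was limited, since a true change of 1.5-fold was recovered in 16.9% of the simulated genes in the Al response of wild type, 13.8% in als3-1 and 4.55% in sog1-7.

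In the list below, counts are given with the replicate block, with the block and the low-rRNA term together, with only the groups compared, and for the fits without 1 library from lowest to highest. The Al response in wild type (408) had 803, 1778, 163 and 212 to 356, with DESeq2 717, on the FPKM scale 213 and with the low-rRNA term 669. In als3-1 (2348) there were 4085, 4736, 1199 and 1362 to 2494, at least 2-fold 1152 and on the FPKM scale 1468. In sog1-7 (257) there were 573, 1102, 78 and 144 to 244, with DESeq2 538, without the low-rRNA libraries 143 and with their term 495.

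For als3-1 minus sog1-7 (249) the same 4 were 411, 714, 164 and 149 to 254, with DESeq2 450, FPKM 129, without the low-rRNA libraries 109 and with their term 375. For als3-1 minus wild type (87) they were 151, 265, 56 and 34 to 95, with DESeq2 217 and FPKM 16. For sog1-7 minus wild type (1) they were 4, 2, 0 and 0 to 0, with DESeq2 3, FPKM 0, without the low-rRNA libraries 0 and with their term 0 (435 genes at unadjusted p under 0.05 in edgeR). The 60 raised genes became 111, 200, 34 and 28 to 86, with DESeq2 123, without the low-rRNA libraries 24 and with their term 95. The 172 lowered genes became 273, 440, 112 and 113 to 155, with DESeq2 297, FPKM 78 and without the low-rRNA libraries 79.

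At 1.5 mM, als3-1 against sog1-7 (1448) had 3136, 5485, 453 and 639 to 1656, at least 2-fold 664, DESeq2 2253, FPKM 870, without the low-rRNA libraries 952 and with their term 3082. The mutants against wild type at 1.5 mM had, for als3-1 (1207), 2510, 3302, 462 and 635 to 940, at least 2-fold 646, DESeq2 1883 and the low-rRNA term 2336. For sog1-7 (1602) they had 3611, 5232, 643 and 583 to 1412, at least 2-fold 555, DESeq2 2602 and the low-rRNA term 3743. At 0 mM, als3-1 against wild type (502) had 1595, 3475, 182 and 154 to 374, at least 2-fold 251, DESeq2 1151, FPKM 255, without the low-rRNA libraries 1027 and with their term 1501. For sog1-7 against wild type at 0 mM (2211) the replicate numbers correlated by −0.05 to 0.22 with 2 of 3 pairs over 0.1, and the counts were 4124, 6492, 1134 and 1208 to 1810, at least 2-fold 774 and with the low-rRNA term 4378.

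The genes shared by wild type and als3-1 (292) were 595, 1139, 108 and 167 to 280, at least 2-fold 188, DESeq2 499, FPKM 161 and with the low-rRNA term 472. Those of als3-1 and sog1-7 (193) were 411, 728, 61 and 119 to 193, DESeq2 375, without the low-rRNA libraries 125 and with their term 352. Those of wild type and sog1-7 (183) were 351, 627, 43 and 119 to 177, DESeq2 329, FPKM 111, without the low-rRNA libraries 118 and with their term 296. Those of all 3 (146) were 288, 512, 39 and 102 to 152, DESeq2 261 and with the low-rRNA term 244. Over the 20 lists and 9 comparisons 76 results passed with the preset correlation, 10 with an estimated correlation and 46 with fry. Of the 76, 10 passed again with an estimated correlation, 41 with fry, 75 with the replicate block and 68 without the low-rRNA libraries, and none reversed. Of the 10, only aluminium resistance still passed with an estimated correlation and without the low-rRNA libraries (adjusted p = 0.0052 in wild type, 0.042 in als3-1 and 0.000536 in sog1-7). Suberin then had 0.137 in wild type and 0.153 in sog1-7. The DNA damage list had 0.0816 for als3-1 minus sog1-7, 0.226 for sog1-7 minus wild type and 0.151 at 1.5 mM, and iron supply 0.226 and 0.151 in the last 2. Phosphate starvation in sog1-7 went from 0.06 to 0.0243.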

Other observations

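The comparisons and gene choices of this part were all made after the data were seen. The p-values of whole lists with an estimated correlation were adjusted here over the lists of both mutants against wild type together. Elsewhere they were adjusted within each comparison, so the values of this part are not on the same scale. A list that did not pass here could pass within its own comparison, which was not tested. At 1.5 mM, 17 of 35 DNA damage response genes were higher in als3-1 than in wild type (22 adjusted over the list alone, adjusted p = 0.0652 with an estimated correlation). SMR7 was higher by 2.99 ± 0.44 (1.74 to 13.9 CPM, n = 3 against 3), ERF115 by 2.90 ± 0.47, XRI1 by 1.85 ± 0.24, BRCA1 by 1.43 ± 0.23 and PARP1 by 0.93 ± 0.13. IRT1 was lower in als3-1 by 2.40 ± 0.19, PLT1 by 1.49 ± 0.25, TIP2;3 by 3.72 ± 0.61 and ATCSLB05 by 4.58 ± 0.50, and EM6 was higher by 4.68 ± 0.87. EM6 had 5.42, 9.72 and 0.304 CPM in als3-1 replicates 2, 3 and 4, and 0.105 to 0.299 CPM in wild type. Of 5 root tissue genes 3 were lower (1 higher and 3 lower adjusted over the list alone, 0.383 with an estimated correlation). Of 15 seed protein genes 8 were higher (12 adjusted over the list alone, 0.31 with an estimated correlation). The seed list score was 1.717, 3.212 and −0.978 in als3-1 replicates 2, 3 and 4. It was −1.164 to −0.533 in wild type, so als3-1 replicate 4 lay within the wild-type range. Over all genes 1207 were called, 552 higher and 655 lower (731 and 175 on the FPKM scale). The count was 2510 with the replicate block, 1117 without the low-rRNA libraries, 635 or 782 without wild type 1.5 mM replicate 2 or 3 and 664 or 661 without als3-1 1.5 mM replicate 2 or 3.

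Against wild type at 1.5 mM, 12 of 17 iron supply genes were lower and 1 higher in sog1-7 (14 and 3 adjusted over the list alone, adjusted p = 0.0578 with an estimated correlation). FRO2 was lower by 3.82 ± 0.25 (70.8 to 4.99 CPM, n = 3 against 3), IRT1 by 3.71 ± 0.20 (69.3 to 5.29 CPM), MYB72 by 5.13 ± 0.87 and MYB10 by 1.47 ± 0.22. FIT1 was not called in the main fit (−0.84, adjusted p = 0.128), but it passed without the low-rRNA libraries (0.0264) and with the replicate block (0.013). RBCS2B was lower by 2.37 ± 0.40 and LHCB2.3 by 4.15 ± 0.63, and QQS was higher by 4.48 ± 0.41. Of 14 photosynthesis genes 6 were lower (11 adjusted over the list alone, 0.31 with an estimated correlation). Of 3 reserve mobilisation genes 2 were higher (3 adjusted over the list alone, 0.31 with an estimated correlation), MLS by 2.02 ± 0.56 and PCK1 by 1.28 ± 0.36. The call of MLS ended without wild type replicate 2 or 4 or sog1-7 replicate 3 or 4 (0.0789 to 0.143), and that of PCK1 without wild type replicate 2, 3 or 4 or sog1-7 replicate 3 or 4 (0.0565 to 0.17). These fits did not use the replicate block. With the block and all libraries MLS and PCK1 passed (adjusted p = 0.000794 and 0.000204). So did ICL, the remaining gene of the list (0.00104, and 0.0604 in the main fit). Of 15 seed protein genes 4 were higher (12 adjusted over the list alone, 0.324 with an estimated correlation). Of 35 DNA damage response genes 0 were higher and 3 lower in sog1-7 (0 and 7 adjusted over the list alone, 0.584 with an estimated correlation, 1 called without the low-rRNA libraries). SMR7 was lower by 1.8 ± 0.47 (adjusted p = 0.032, 0.0234 with the replicate block), and its call ended in 4 fits without 1 library (up to 0.118). Over all genes 1602 were called, 811 higher and 791 lower (1448 and 176 on the FPKM scale). The count was 3611 with the replicate block, 2347 without the low-rRNA libraries, 727, 855 or 946 without wild type 1.5 mM replicate 2, 3 or 4 and 593 or 583 without sog1-7 1.5 mM replicate 3 or 4.

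The term for the 3 low-rRNA libraries passed for 4077 genes higher and 3876 lower, 36.7% of the genes tested.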
